A study of Homo sapiens with 40 samples.

How the data were processed

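Cultured LNCaP and U937 cells were profiled on 1-colour Affymetrix Human Gene 1.0 ST arrays. Per the labels' protocols, 800000 LNCaP or 600000 U937 cells were plated in RPMI-1640 with serum and treated 48 h later. Merle 23 was given at 1000 nM, PMA and bryostatin 1 each at 100 nM, and controls got 0.1% DMSO. Exposure lasted 6 h in LNCaP and 8 h in U937. Total RNA was extracted with Trizol, all samples had a RNA integrity number above 9, and 100 ng were amplified and labelled as sense cDNA. Each of the 8 groups held 5 arrays, and with 1 time per line, line and time could not be told apart. The deposited values were log2 probe set intensities after RMA, per the labels, without a version, and the authors' further filters were not stated. Per the design text, the authors tested them with one-way models and planned contrasts in Partek Genomics Suite 6.5 and with Storey q-values. Array medians lay between 5.29 and 5.43, no columns were identical, and correlations between arrays of a group lay between 0.981 and 0.998. The number of arrays limits the precision.

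The value table held 28869 probe sets, of which 19310 had exactly 1 gene symbol in the platform's probe table, 1752 had several and 7807 had none. The probe table had 21062 entries with a gene, and 19279 were also matched to current symbols by Entrez number. For each of 18377 genes the probe set with the highest mean over the 40 arrays was used. The 3 probe sets of TNF gave equal values. Genome positions were not used, since the labels name no build.

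Contrasts were fitted in R 4.3.3 with limma 3.58.1, as a one-way model of the 8 groups over 40 arrays with empirical Bayes moderation. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes of a contrast, and a gene was called at an adjusted p under 0.05. A further count took genes that also changed at least 2-fold. Within each line 6 contrasts were made: each compound against DMSO, bryostatin 1 against PMA, and Merle 23 against PMA and against bryostatin 1. The difference of an effect between the lines was tested as an interaction for each compound and for bryostatin 1 against PMA. Intervals are 95% intervals of the moderated model. Tables were read and figures drawn with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

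Before the data were examined, 29 gene lists with 600 entries were written from textbook knowledge, of which 546 were measured. They held immediate early and AP-1 factors, ERK feedback genes, NF-kB targets, cytokines and chemokines, matrix proteases, EGF family genes, integrins, androgen response genes, DNA replication and mitosis genes, CDK inhibitors, MYC targets, death receptor and BH3 genes and anti-apoptotic genes. They also held monocyte and myeloid progenitor genes, PKC and C1 domain genes, cholesterol, unfolded protein, heat shock, interferon, hypoxia and epithelial-mesenchymal genes, core controls, and markers of prostate epithelium, myeloid cells, fibroblasts, lymphocytes and endothelium. Camera tested each list with a preset correlation of 0.01 and again with an estimated correlation, adjusted over all lists and the 6 contrasts of a line, and separately over the contrasts between lines. List members were also adjusted over the list alone.

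The genes named were set by a rule written before the data were examined. It took the 6 largest rises and 6 largest falls among called genes whose groups of arrays did not overlap, for each compound against DMSO and for bryostatin 1 against PMA in each line. It took up to 4 called members of each list past camera and up to 2 of the others, 4 rises and 4 falls for the other contrasts of Merle 23, and 5 in each direction between the lines. PKC list members, TNF, CXCL8, TRAF1, EGR1, FOS, DUSP6, MMP9, KLK3, CDKN1A and MYC could always be named, called or not, and a gene taken for 1 contrast could be named in others. Not every gene that the rule gives was named.

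The distance between a pair of group profiles was the root mean square difference of group means over all genes, after subtraction of the part expected from the spread between arrays. The distance of Merle 23 to bryostatin 1 minus that to PMA was tested by exchanging the PMA and bryostatin 1 labels over their 10 arrays in every way. Shared calls were counted per direction, with the count for independent calls, with unchanged groups simulated 20 times, and with DMSO arrays split between compounds.

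The labels number the arrays of a group from 1 to 5 without saying whether numbers were cultured together. Residuals of arrays with the same number had a median correlation over genes of 0.411 in LNCaP (lowest 0.110) and 0.335 in U937 (lowest 0.142), against -0.0716 and -0.152 for different numbers. A fit with line and number as a block was therefore an alternative, and its value is given where it ends or makes a call or moves a count by over 1.5 times. Other alternatives were a filter on dim genes, quantile normalization within a line, median centring, all probe sets, the mean of a gene's probe sets, only the arrays of the line, the plain contrast with either adjustment, trend and robust moderation, array weights, and leaving out each array. P-values measure array spread only. Simulated changes were put into unchanged groups of 18377 genes to check the contrast: limma called 92.5% of genes changed by 0.5 and 98.5% of those changed by 2 (log2), with 8 false calls.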

Results

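Gene expression was measured by array in a pair of human cell lines treated with activators of protein kinase C (PKC). LNCaP is a prostate adenocarcinoma line and U937 a leukemic monocyte lymphoma line. PMA is a phorbol ester and bryostatin 1 a macrocyclic lactone, and both bind the C1 domains of PKC. Merle 23 is named by its code in the labels. LNCaP cells were sampled after 6 h and U937 cells after 8 h. Merle 23 was given at 1000 nM, PMA and bryostatin 1 each at 100 nM, and control cells got 0.1% DMSO. Each of the 8 groups held 5 arrays, a number that limits the precision. Array medians of the log2 RMA intensities lay between 5.29 and 5.43. No detection calls were used, so a level below these medians is not shown to be above background, and a change from or to such a level is a lower bound in size. The series title names a difference between bryostatin 1 and phorbol ester in how long expression is changed. With 1 time per line, no duration was analysed. The comparisons ask which genes each compound changed, and where compounds and lines differed. Changes are log2 differences ± SE (n = 5 arrays per group). Each SE pools all 8 groups of both lines, so SE and p need not reflect the groups compared. P-values measure array spread only, since the labels do not say whether replicates were separate cultures.

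PMA in LNCaP for 6 h raised many matrix protease, adhesion and NF-kB target genes. CLDN1, which encodes a tight junction claudin (probe set 8092726), stood at 4.34 ± 0.07 in DMSO and 10.41 ± 0.22 in PMA (mean ± SD, n = 5), a change of 6.07 ± 0.13. ITGA2, an integrin subunit that binds collagen (probe set 8105267), rose by 5.92 ± 0.14, and MMP10, a stromelysin that degrades matrix (probe set 7951259), by 4.85 ± 0.13. SYTL2, a Rab27 effector in vesicle traffic, rose by 4.95 ± 0.12, EDN1, which encodes a vasoconstrictor peptide, by 4.69 ± 0.17, and the monocyte chemokine CCL2 by 4.53 ± 0.27. The largest fall named was in TXNIP, which binds thioredoxin and restrains glucose uptake, at -3.52 ± 0.15. The arrestin-like ARRDC3 changed by -3.13 ± 0.11, the scaffold SASH1 by -2.58 ± 0.09 and the epithelial transcription factor GRHL2 by -2.53 ± 0.08. The highest adjusted p of these 10 genes was 3.93e-17 (limma).

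Signalling genes rose as groups. Of the 25 measured immediate early and AP-1 factors, 18 rose, none fell and 7 did not pass (18 and 0 adjusted over the list alone, camera adjusted p = 1.02e-11). Among them were the stress factor ATF3 (3.19 ± 0.14), IER3, which protects from cell death (3.11 ± 0.15), the zinc finger factor KLF6 (2.80 ± 0.15) and EGR1 (2.56 ± 0.37), while FOS, a partner of JUN, rose by 0.89 ± 0.10. Among 18 ERK pathway feedback genes, 13 rose, 1 fell and 4 did not pass (13 and 1 adjusted over the list alone, camera adjusted p = 8.09e-08). The MAP kinase phosphatases DUSP10 and DUSP5 rose by 3.35 ± 0.12 and 3.31 ± 0.15, and ERRFI1, an inhibitor of the EGF receptor, by 3.32 ± 0.16. NF-kB targets gave the highest median among the lists: of 26, 20 rose, none fell and 6 did not pass (20 and 0 adjusted over the list alone, camera adjusted p = 2.12e-17). TNFAIP3, a ubiquitin-editing brake on NF-kB, rose by 4.20 ± 0.20, the neutrophil chemokine CXCL8 by 4.08 ± 0.23, the cytokine TNF by 2.84 ± 0.26 and the adaptor TRAF1 by 2.13 ± 0.09. In the list of 27 secreted cytokines and chemokines, 10 rose, none fell and 17 did not pass (10 and 0 adjusted over the list alone, camera adjusted p = 2.12e-04, adjusted p = 0.0520 with an estimated correlation).

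Of the 20 genes of matrix proteases and the plasminogen system, 12 rose, 1 fell and 7 did not pass (12 and 1 adjusted over the list alone, camera adjusted p = 1.21e-08). MMP7, or matrilysin, rose by 4.20 ± 0.11, the elastase MMP12 by 3.52 ± 0.17 and the collagenase MMP1 by 3.11 ± 0.21. Of 21 integrin and cell adhesion genes, 13 rose, none fell and 8 did not pass (13 and 0 adjusted over the list alone, camera adjusted p = 1.26e-07). Of 21 epithelial and mesenchymal state genes, 14 rose, 2 fell and 5 did not pass (14 and 2 adjusted over the list alone, camera adjusted p = 2.60e-05). Many prostate and proliferation genes moved the other way. Of 21 androgen response genes, 2 rose, 14 fell and 5 did not pass (3 and 15 adjusted over the list alone, camera adjusted p = 2.83e-04, adjusted p = 0.0675 with an estimated correlation). KLK3, which encodes prostate-specific antigen, changed by -1.34 ± 0.07, its relative KLK2 by -1.54 ± 0.09 and the prostate transporter SLC45A3 by -2.01 ± 0.15. Of 12 prostate epithelium markers, which share members with that list, 4 rose, 8 fell and 0 did not pass (4 and 8 adjusted over the list alone, camera adjusted p = 0.0198, adjusted p = 0.0592 with an estimated correlation). HOXB13, a homeobox factor of prostate, changed by -1.64 ± 0.10. Of 34 DNA replication and G1/S genes, 1 rose, 29 fell and 4 did not pass (1 and 29 adjusted over the list alone, camera adjusted p = 1.13e-08, adjusted p = 0.0642 with an estimated correlation). Among them was ORC1, a subunit of the origin recognition complex, at -1.31 ± 0.09. Of 33 mitosis and G2/M genes, none rose, 31 fell and 2 did not pass (0 and 31 adjusted over the list alone, camera adjusted p = 2.22e-12, adjusted p = 0.0637 with an estimated correlation). The mitotic kinesin KIF20A changed by -2.12 ± 0.13 and the spindle checkpoint kinase BUB1B by -1.67 ± 0.10.

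MYC itself, a growth-promoting transcription factor, changed by -1.42 ± 0.15 with PMA in LNCaP. Among MYC and its nucleolar targets (24 measured), 1 rose, 14 fell and 9 did not pass (1 and 16 adjusted over the list alone, camera adjusted p = 2.18e-04, adjusted p = 0.157 with an estimated correlation), and the RNA polymerase I subunit POLR1B changed by -1.48 ± 0.12. Of 16 CDK inhibitors and growth arrest genes, 9 rose, 4 fell and 3 did not pass (9 and 4 adjusted over the list alone, camera adjusted p = 0.00559). The inhibitors CDKN2B and CDKN1A rose by 2.85 ± 0.14 and 0.87 ± 0.09. The list of death receptors, ligands and BH3 genes (21 measured) gave 13 rises, 2 falls and 6 that did not pass (13 and 2 adjusted over the list alone, camera adjusted p = 2.40e-04). An example was the BH3-only gene PMAIP1 up by 1.71 ± 0.13. Anti-apoptotic genes (9 measured) gave 5 rises, 1 fall and 3 that did not pass (6 and 1 adjusted over the list alone, camera adjusted p = 0.0376, adjusted p = 0.0840 with an estimated correlation), and among them MCL1 rose by 0.93 ± 0.06 and BIRC2 by 1.09 ± 0.10. Of 23 unfolded protein and amino acid response genes, 16 rose, 1 fell and 6 did not pass (16 and 1 adjusted over the list alone, camera adjusted p = 7.15e-07). DDIT3, a transcription factor of prolonged stress, rose by 2.42 ± 0.10, the glutathione-degrading enzyme CHAC1 by 2.24 ± 0.13 and the sestrin SESN2 by 2.29 ± 0.11. For interferon-stimulated genes, 28 in number, 15 rose, 1 fell and 12 did not pass (16 and 1 adjusted over the list alone, camera adjusted p = 6.83e-05). Members included IRF1, an interferon regulatory factor, at 2.92 ± 0.13 and the antiviral enzyme RSAD2 at 2.49 ± 0.12. Among 30 PKC isoforms and other C1 domain proteins, 13 rose, 3 fell and 14 did not pass (13 and 3 adjusted over the list alone, camera adjusted p = 0.00558). The conventional isoform PRKCA rose by 2.21 ± 0.11, and protein kinase D1, encoded by PRKD1, changed by -1.50 ± 0.10. Over both lines camera with its preset correlation called 184 of 348 tests of a list, and 108 of these also passed with an estimated correlation.

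In total 7769 of 18377 genes differed between PMA and DMSO in LNCaP (limma, adjusted p under 0.05), with 3331 higher and 4438 lower with PMA. At least 2-fold changes were seen in 636 rises and 364 falls.

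**Figure D1:**
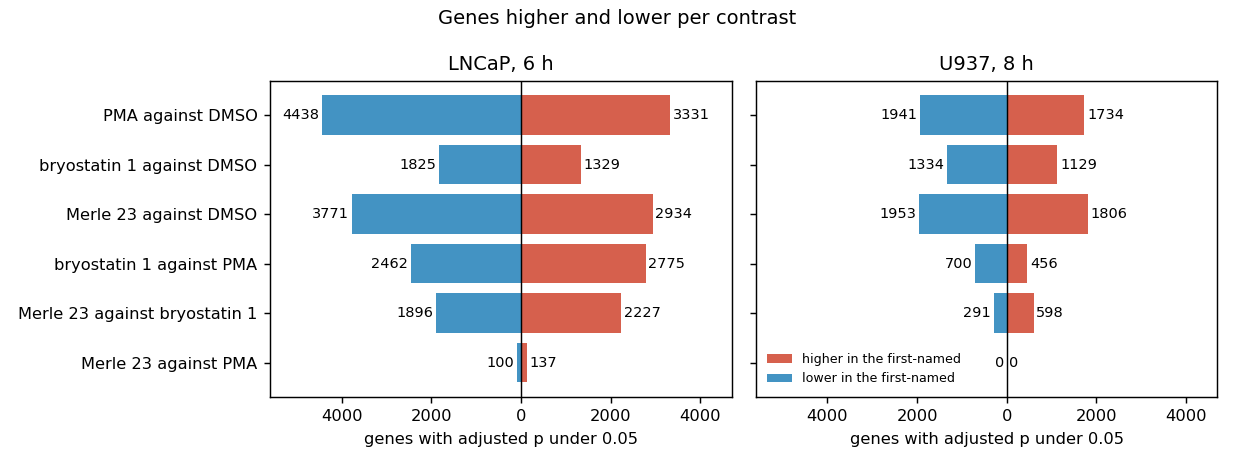
Genes with an adjusted p under 0.05 (limma, 5 arrays per group) per contrast, as the number of genes on the x axis, with bars to the right for genes higher in the first-named group and to the left for genes lower in it. PMA gave 3331 rises and 4438 falls in LNCaP at 6 h, and the bar of Merle 23 against PMA is the shortest in both lines.

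Bryostatin 1 in LNCaP, at the same 100 nM and 6 h, raised several of the genes that led with PMA by less, while TNF, EGR1, FOS and MYC did not pass. CLDN1 rose by 3.81 ± 0.13, ITGA2 by 3.66 ± 0.14, MMP10 by 3.53 ± 0.13 and SYTL2 by 3.23 ± 0.12. RAET1L, a ligand of the receptor NKG2D, rose by 3.28 ± 0.12, the matrilysin MMP7 by 2.80 ± 0.11 and the collagenase MMP13 by 2.28 ± 0.13. Falls were seen in RANBP3L (-1.67 ± 0.12), TXNIP (-1.31 ± 0.15), the growth factor receptor IGF1R (-1.08 ± 0.19) and the retinoic acid receptor RARB (-1.07 ± 0.07). TNF differed from DMSO by 0.13 ± 0.26 (adjusted p = 0.805, limma), EGR1 by 0.26 ± 0.37 (adjusted p = 0.709), FOS by 0.14 ± 0.10 (adjusted p = 0.418) and MYC by -0.03 ± 0.15 (adjusted p = 0.920).

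Of 20 matrix protease and plasminogen genes, 10 rose, none fell and 10 did not pass (10 and 0 adjusted over the list alone, camera adjusted p = 4.74e-11) with bryostatin 1 in LNCaP, and of 21 integrin and adhesion genes, 12 rose, none fell and 9 did not pass (13 and 0 adjusted over the list alone, camera adjusted p = 8.56e-11). Of 26 NF-kB targets, 15 rose, none fell and 11 did not pass (16 and 0 adjusted over the list alone, camera adjusted p = 1.90e-10). Among them were TNFAIP3 at 1.10 ± 0.20 and CXCL8 at 0.86 ± 0.23. Secreted cytokines and chemokines (27 measured) gave 7 rises, no falls and 20 that did not pass (7 and 0 adjusted over the list alone, camera adjusted p = 0.00246, adjusted p = 0.103 with an estimated correlation). Among them was CCL2 at 2.12 ± 0.27. The list of 25 immediate early and AP-1 factors held 4 rises, 1 fall and 20 that did not pass (4 and 1 adjusted over the list alone, camera adjusted p = 0.138), and KLF4, a zinc finger factor of epithelia, was among the rises at 0.85 ± 0.12. Of 18 ERK feedback genes, 7 rose, none fell and 11 did not pass (7 and 0 adjusted over the list alone, camera adjusted p = 8.15e-04). Members included ERRFI1 at 0.97 ± 0.16 and DUSP5 at 0.78 ± 0.15. DNA replication and G1/S genes fell: of 34, none rose, 25 fell and 9 did not pass (0 and 31 adjusted over the list alone, camera adjusted p = 2.41e-18), and the replication kinase CDC7 changed by -0.75 ± 0.11. Of 33 mitosis genes, none rose, 12 fell and 21 did not pass (0 and 15 adjusted over the list alone, camera adjusted p = 1.21e-06, adjusted p = 0.192 with an estimated correlation). MYC and its nucleolar targets gave no rises, 8 falls and 16 that did not pass (0 and 13 adjusted over the list alone, camera adjusted p = 1.38e-05, adjusted p = 0.0971 with an estimated correlation). CDK inhibitors and arrest genes gave 10 rises, 2 falls and 4 that did not pass (11 and 2 adjusted over the list alone, camera adjusted p = 0.00324). Among them was CDKN1A at 0.75 ± 0.09. Of 21 androgen response genes, 2 rose, 8 fell and 11 did not pass (3 and 10 adjusted over the list alone, camera adjusted p = 0.00746, adjusted p = 0.175 with an estimated correlation). Examples were KLK3 at -0.42 ± 0.07 and KLK2 at -0.67 ± 0.09. The unfolded protein and amino acid response list held 4 rises, 1 fall and 18 that did not pass (4 and 1 adjusted over the list alone, camera adjusted p = 0.271, median log2 -0.00357 and mean 0.07 with the test pointing up), and the amino acid transporter subunit SLC3A2 was at 0.83 ± 0.08. Of 30 PKC and C1 domain genes, 8 rose, 3 fell and 19 did not pass (9 and 5 adjusted over the list alone, camera adjusted p = 0.0332, adjusted p = 0.0731 with an estimated correlation, adjusted p = 0.0655 with the replicate block). Members included PRKCA at 1.06 ± 0.11 and PRKD1 at -0.49 ± 0.10.

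Bryostatin 1 changed 3154 genes in LNCaP (limma), 1329 upward and 1825 downward, of which 93 and 6 changed at least 2-fold. With the replicate number as a block the count was 5632, and with only the LNCaP arrays in the model it was 1978.

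Merle 23 in LNCaP for 6 h, at 1000 nM, gave leading rises close in size to those of PMA, while estimates for TXNIP, EGR1, FOS and KIF20A were smaller. CLDN1 rose by 5.84 ± 0.13, ITGA2 by 5.69 ± 0.14, SYTL2 by 4.84 ± 0.12, MMP10 by 4.84 ± 0.13, CCL2 by 4.42 ± 0.27 and RAET1L by 4.25 ± 0.12. TXNIP changed by -2.58 ± 0.15 and ARRDC3 by -2.37 ± 0.11. Among 26 NF-kB targets 20 rose, none fell and 6 did not pass (20 and 0 adjusted over the list alone, camera adjusted p = 1.84e-18), and TNFAIP3, CXCL8 and TNF rose by 3.73 ± 0.20, 3.42 ± 0.23 and 2.05 ± 0.26. Of 25 immediate early factors, 18 rose, none fell and 7 did not pass (19 and 0 adjusted over the list alone, camera adjusted p = 5.06e-10). Among them were EGR1 at 1.44 ± 0.37 and FOS at 0.47 ± 0.10. ERK feedback genes (18 measured) gave 14 rises, 1 fall and 3 that did not pass (14 and 1 adjusted over the list alone, camera adjusted p = 8.24e-09). Of 20 matrix protease genes, 12 rose, none fell and 8 did not pass (12 and 0 adjusted over the list alone, camera adjusted p = 7.53e-09). Of 33 mitosis genes, none rose, 26 fell and 7 did not pass (0 and 29 adjusted over the list alone, camera adjusted p = 5.53e-09, adjusted p = 0.115 with an estimated correlation). Among them was KIF20A at -1.47 ± 0.13. MYC changed by -0.97 ± 0.15 and KLK3 by -1.14 ± 0.07. In the unfolded protein and amino acid response list 17 rose, none fell and 6 did not pass (17 and 0 adjusted over the list alone, camera adjusted p = 3.07e-08). Members included DDIT3 at 1.94 ± 0.10 and CHAC1 at 1.93 ± 0.13. PRKCA rose by 2.07 ± 0.11 and TRAF1 by 1.80 ± 0.09. In all 6705 genes differed from DMSO (limma), 2934 higher and 3771 lower, 538 and 192 of them at least 2-fold.

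The direct contrast in LNCaP, at equal doses and times, asked which genes differed between bryostatin 1 and PMA. EDN1 was lower with bryostatin 1 at -4.41 ± 0.17, as were the matricellular gene CCN1 at -3.32 ± 0.17, TCIM at -3.31 ± 0.13 and the membrane protein EMP1 at -3.22 ± 0.11. CXCL8, TNFAIP3 and TNF differed by -3.22 ± 0.23, -3.10 ± 0.20 and -2.71 ± 0.26. ARRDC3 was higher with bryostatin 1 by 3.26 ± 0.11, the prostaglandin F receptor PTGFR by 2.32 ± 0.09, TXNIP by 2.20 ± 0.15, the transcription factor GATA2 by 2.06 ± 0.19 and GRHL2 by 2.01 ± 0.08.

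Of 25 immediate early factors in this contrast, none were higher with bryostatin 1, 18 lower and 7 did not pass (0 and 18 adjusted over the list alone, camera adjusted p = 4.40e-17). ATF3 differed by -2.93 ± 0.14, KLF6 by -2.55 ± 0.15, EGR1 by -2.30 ± 0.37 and FOS by -0.75 ± 0.10. NF-kB targets gave none higher, 19 lower and 7 that did not pass (0 and 20 adjusted over the list alone, camera adjusted p = 5.13e-21). The ERK feedback list gave 1 higher, 10 lower and 7 that did not pass (1 and 10 adjusted over the list alone, camera adjusted p = 8.24e-09). Among them were DUSP10 at -2.68 ± 0.12 and DUSP5 at -2.53 ± 0.15. Of 23 unfolded protein and amino acid response genes, 1 was higher, 15 lower and 7 did not pass (2 and 15 adjusted over the list alone, camera adjusted p = 2.31e-08). CHAC1 differed by -2.78 ± 0.13, DDIT3 by -1.99 ± 0.10 and SESN2 by -1.90 ± 0.11. Interferon-stimulated genes gave 1 higher, 13 lower and 14 that did not pass (1 and 13 adjusted over the list alone, camera adjusted p = 2.89e-04). Examples were IRF1 at -2.44 ± 0.13 and RSAD2 at -2.16 ± 0.12. Matrix protease genes gave 1 higher, 11 lower and 8 that did not pass (1 and 11 adjusted over the list alone, camera adjusted p = 3.48e-06). Members included MMP12 at -1.63 ± 0.17 and the urokinase gene PLAU at -1.72 ± 0.11. For ITGA2 and CLDN1 the differences were -2.26 ± 0.14 and -2.26 ± 0.13. Of 33 mitosis genes, 26 were higher with bryostatin 1, none lower and 7 did not pass (27 and 0 adjusted over the list alone, camera adjusted p = 5.92e-12, adjusted p = 0.0669 with an estimated correlation). Among them were KIF20A at 1.70 ± 0.13 and BUB1B at 1.13 ± 0.10. Of 21 androgen response genes, 11 were higher, 2 lower and 8 did not pass (12 and 2 adjusted over the list alone, camera adjusted p = 2.89e-04, adjusted p = 0.0675 with an estimated correlation). Examples were KLK3 at 0.92 ± 0.07 and SLC45A3 at 1.51 ± 0.15. MYC was higher by 1.39 ± 0.15, PRKD1 by 1.01 ± 0.10, and PRKCA and PMAIP1 were lower at -1.16 ± 0.11 and -2.03 ± 0.13. For CDKN1A the difference was -0.13 ± 0.09 (adjusted p = 0.369, limma, 95% interval -0.32 to 0.06). Across genes 5237 differed (limma), 2775 higher with bryostatin 1 and 2462 lower, 108 and 349 of them at least 2-fold.

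Merle 23 and PMA differed little in LNCaP, at 1000 and 100 nM. TXNIP was higher with Merle 23 by 0.94 ± 0.15 and ARRDC3 by 0.76 ± 0.11, and the keratin KRT75 was lower at -1.09 ± 0.11. ATF3 and TCIM were lower at -0.76 ± 0.14 and -0.75 ± 0.13 (adjusted p = 0.00171 and 5.34e-04, limma). With only the LNCaP arrays in the model their adjusted p were 0.118 and 0.0616, and over all alternatives they ran from 5.06e-07 to 0.118 and from 2.66e-07 to 0.0616. TNF differed by -0.79 ± 0.26 (95% interval -1.32 to -0.26), CXCL8 by -0.66 ± 0.23 (-1.12 to -0.20) and EGR1 by -1.12 ± 0.37 (-1.87 to -0.36), with adjusted p of 0.146, 0.174 and 0.156 (limma). With the replicate block these were 8.18e-05, 5.53e-04 and 1.42e-08, the lowest of their alternatives, while the highest were 0.351, 0.373 and 0.366. With only the LNCaP arrays EGR1 had an adjusted p of 0.0146, and without Merle 23 replicate 2 TNF differed by -0.97 with an adjusted p of 0.0435. Of 25 immediate early factors, none were higher with Merle 23, 5 lower and 20 did not pass (0 and 11 adjusted over the list alone, camera adjusted p = 9.90e-12). Of 26 NF-kB targets, none were higher, 1 lower and 25 did not pass (0 and 5 adjusted over the list alone, camera adjusted p = 1.15e-07). Of 33 mitosis genes, 12 were higher with Merle 23, none lower and 21 did not pass (15 and 0 adjusted over the list alone, camera adjusted p = 2.75e-18).

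For this pair 237 genes differed (limma), 137 higher with Merle 23 and 100 lower, 1 and 1 of them at least 2-fold. The 95% interval of the difference excluded a 2-fold change for 18353 of 18377 genes, among them 982 of the 1000 genes that PMA changed at least 2-fold. The count was 47 with only the LNCaP arrays, 1276 with the replicate block, 591 with array weights and 447 without the 4 LNCaP arrays numbered 1. Leaving out 1 array moved it from 121 (without Merle 23 replicate 4) to 338 (without Merle 23 replicate 2). It was 144 without PMA replicate 2, 156 without PMA replicate 4 and 144 without Merle 23 replicate 3.

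Merle 23 and bryostatin 1, at 1000 and 100 nM, differed in LNCaP in several genes that also set bryostatin 1 apart from PMA. EDN1 was higher with Merle 23 by 3.51 ± 0.17, EMP1 by 2.90 ± 0.11, TNFAIP3 by 2.63 ± 0.20, CXCL8 by 2.56 ± 0.23 and TNF by 1.92 ± 0.26. ARRDC3 was lower at -2.50 ± 0.11, PTGFR at -1.69 ± 0.09, GRHL2 at -1.45 ± 0.08, MYC at -0.93 ± 0.15 and KLK3 at -0.72 ± 0.07. Of 26 NF-kB targets, 19 were higher, none lower and 7 did not pass (19 and 0 adjusted over the list alone, camera adjusted p = 2.69e-22). The unfolded protein and amino acid response list gave 16 higher, none lower and 7 that did not pass (16 and 0 adjusted over the list alone, camera adjusted p = 1.17e-10). In all 4123 genes differed (limma), 2227 higher with Merle 23 and 1896 lower, 237 and 38 at least 2-fold, and with the replicate block the count was 6342. The root mean square distance of the Merle 23 profile over all genes, less the part due to array spread, was 0.266 to bryostatin 1 and 0.0374 to PMA. Their difference of 0.228 gave p = 0.206 in a two-sided exact permutation test over all splits of 5 against 5 arrays, whose smallest p is 0.00794. A difference of squared distances, tried after the data were seen, gave p = 0.00794 in the same exact test. With labels exchanged within replicate numbers, also tried later, the difference was 0.185 (exact permutation p = 0.438, where the smallest possible is 0.0625). Within each replicate number the Merle 23 array lay closer to the PMA array in 5 of 5 numbers, at 0.163 to 0.196 against 0.282 to 0.350 to bryostatin 1.

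**Figure D2:**
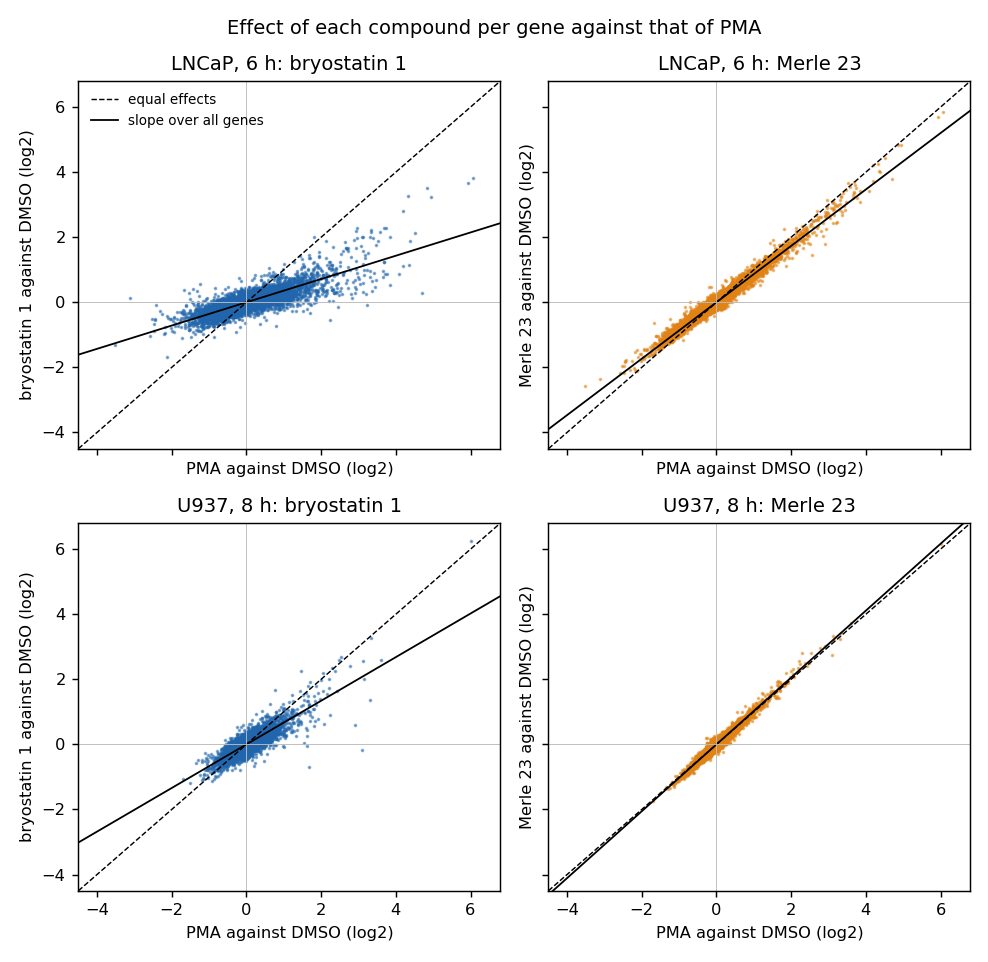
Log2 effect of bryostatin 1 (left) and Merle 23 (right) on each of 18377 genes against that of PMA, all against the same DMSO arrays, in LNCaP at 6 h (top) and U937 at 8 h (bottom). The solid lines have the slopes over all genes (0.358 and 0.867 in LNCaP, 0.670 and 1.03 in U937) after removal of the part that shared controls give, and the dashed lines mark equal effects.

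PMA in U937 for 8 h raised many NF-kB target and monocyte differentiation genes. CXCL10, an interferon-inducible chemokine (probe set 8101126), stood at 4.46 ± 0.09 in DMSO and 10.47 ± 0.03 in PMA (mean ± SD, n = 5), a change of 6.01 ± 0.33. DCSTAMP, a membrane protein of cell fusion in the myeloid lineage (probe set 8147830), rose by 3.59 ± 0.09, TNFAIP3 by 3.34 ± 0.20, IER3 by 3.30 ± 0.15, the kinase SGK1 by 3.14 ± 0.18 and the Notch coactivator MAML2 by 3.12 ± 0.18. Falls were smaller: the nucleotide receptor P2RY2 changed by -1.69 ± 0.08, LAMP5 by -1.52 ± 0.10 and the homeobox gene IRX3 by -1.24 ± 0.11. Of 26 NF-kB targets, 22 rose, none fell and 4 did not pass (24 and 0 adjusted over the list alone, camera adjusted p = 2.60e-43). TNF rose by 3.10 ± 0.26, the cytokine IL1B by 2.91 ± 0.16, CXCL8 by 2.44 ± 0.23, the adhesion receptor ICAM1 by 2.22 ± 0.09 and TRAF1 by 0.64 ± 0.09. Secreted cytokines and chemokines (27 measured) gave 13 rises, no falls and 14 that did not pass (14 and 0 adjusted over the list alone, camera adjusted p = 1.91e-11). Of 33 monocyte and macrophage differentiation genes, 17 rose, 1 fell and 15 did not pass (17 and 2 adjusted over the list alone, camera adjusted p = 1.18e-10). Among them MMP9, a gelatinase of macrophages, rose by 1.99 ± 0.08, the receptor TLR2 by 1.82 ± 0.10 and the integrin subunit ITGAX by 1.67 ± 0.15. Of 19 myeloid progenitor genes, none rose, 10 fell and 9 did not pass (0 and 12 adjusted over the list alone, camera adjusted p = 5.37e-08). GFI1, a repressor in progenitors, changed by -0.86 ± 0.09 and MS4A3, a granulocyte and monocyte progenitor gene, by -1.05 ± 0.08.

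Of 25 immediate early factors in U937 with PMA, 17 rose, none fell and 8 did not pass (18 and 0 adjusted over the list alone, camera adjusted p = 3.87e-14). Among them were EGR1 at 1.67 ± 0.37, EGR3 at 1.63 ± 0.17 and FOS at 1.04 ± 0.10. The ERK feedback list (18 measured) gave 10 rises, no falls and 8 that did not pass (10 and 1 adjusted over the list alone, camera adjusted p = 6.90e-08). Examples were the phosphatases DUSP4, DUSP10 and DUSP6 at 1.64 ± 0.11, 1.53 ± 0.12 and 1.00 ± 0.15. Of 24 MYC and nucleolar target genes, none rose, 18 fell and 6 did not pass (0 and 18 adjusted over the list alone, camera adjusted p = 2.51e-12). MYC changed by -0.75 ± 0.15, the ribosome assembly factor RRS1 by -0.85 ± 0.08 and POLR1B by -0.71 ± 0.12. CDK inhibitors and arrest genes gave 7 rises, 1 fall and 8 that did not pass (7 and 1 adjusted over the list alone, camera adjusted p = 0.00111). Members included CDKN1A at 1.55 ± 0.09 and CDKN1B at 0.92 ± 0.08. Of 33 mitosis genes, 9 rose, none fell and 24 did not pass (9 and 0 adjusted over the list alone, camera adjusted p = 2.35e-05, adjusted p = 0.315 with an estimated correlation). Among them were the phosphatase CDC25C at 0.61 ± 0.08 and the kinesin KIF14 at 0.58 ± 0.13. DNA replication and G1/S genes gave 2 rises, 8 falls and 24 that did not pass (2 and 8 adjusted over the list alone, camera adjusted p = 0.0810, adjusted p = 0.0316 with the replicate block). Anti-apoptotic genes gave 4 rises, 2 falls and 3 that did not pass (6 and 2 adjusted over the list alone, camera adjusted p = 0.0135). Among them was BCL2A1 at 1.65 ± 0.09. In the list of death receptors, ligands and BH3 genes 7 rose, 2 fell and 12 did not pass (7 and 2 adjusted over the list alone, camera adjusted p = 0.00382), and the death ligand TNFSF10 changed by -1.02 ± 0.19. Interferon-stimulated genes gave 4 rises, 3 falls and 21 that did not pass (4 and 4 adjusted over the list alone, camera adjusted p = 0.314), although the RNA sensor IFIH1 rose by 2.48 ± 0.13. Of 30 PKC and C1 domain genes, 5 rose, 5 fell and 20 did not pass (5 and 6 adjusted over the list alone, camera adjusted p = 0.788). Matrix protease genes gave 5 rises, no falls and 15 that did not pass (5 and 0 adjusted over the list alone, camera adjusted p = 5.56e-04). Integrin and adhesion genes gave 7 rises, 2 falls and 12 that did not pass (7 and 3 adjusted over the list alone, camera adjusted p = 0.0368, adjusted p = 0.188 with an estimated correlation, adjusted p = 0.0528 with the replicate block). In total 3675 genes differed from DMSO (limma), 1734 higher and 1941 lower, 144 and 28 of them at least 2-fold, and with the replicate block the count was 5633.

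**Figure D3:**
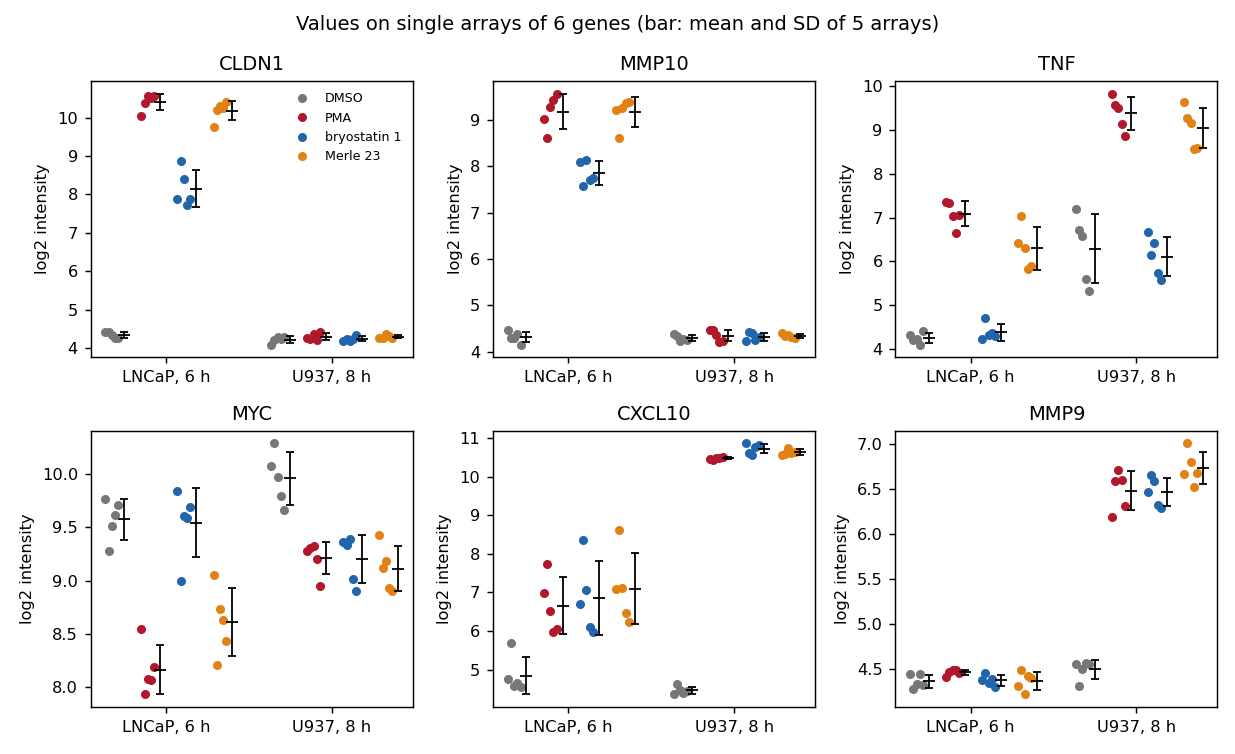
Log2 intensity of 6 genes on each of the 40 arrays, with LNCaP at 6 h on the left and U937 at 8 h on the right of each panel, and black bars for the mean and SD of the 5 arrays of a group. TNF stood at 9.38 ± 0.38 with PMA, 6.11 ± 0.46 with bryostatin 1 and 6.29 ± 0.79 with DMSO in U937, while CXCL10 stood at 10.47 ± 0.03 with PMA and 10.73 ± 0.13 with bryostatin 1.

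Bryostatin 1 in U937, at 100 nM for 8 h, raised the same leading chemokine, while TNF did not pass. CXCL10 rose by 6.26 ± 0.33, TNFAIP3 by 3.26 ± 0.20, the orphan receptor GPR34 by 2.69 ± 0.14, IFIH1 by 2.61 ± 0.13, DCSTAMP by 2.59 ± 0.09 and MAML2 by 2.58 ± 0.18. LAMP5 changed by -1.19 ± 0.10, the cyclin CCND2 by -1.12 ± 0.12 and IRX3 by -0.94 ± 0.11. TNF differed from DMSO by -0.18 ± 0.26 (adjusted p = 0.850, limma, 95% interval -0.70 to 0.35). EGR1 differed by -0.70 ± 0.37 (adjusted p = 0.279, over the alternatives 0.660 down to 2.30e-06 with the replicate block) and DUSP6 by 0.33 ± 0.15 (adjusted p = 0.148, likewise 0.431 down to 0.0288). Among 26 targets of NF-kB 20 rose, none fell and 6 did not pass (21 and 0 adjusted over the list alone, camera adjusted p = 1.54e-37). Members included the NF-kB precursor gene NFKB2 at 2.26 ± 0.08, ICAM1 at 1.73 ± 0.09, CXCL8 at 1.63 ± 0.23 and TRAF1 at 0.32 ± 0.09. Of 33 monocyte and macrophage genes, 15 rose, 1 fell and 17 did not pass (16 and 1 adjusted over the list alone, camera adjusted p = 6.93e-15). Among them were MMP9 at 1.97 ± 0.08, ITGAX at 1.17 ± 0.15 and TLR2 at 1.10 ± 0.10. Myeloid progenitor genes gave no rises, 8 falls and 11 that did not pass (1 and 8 adjusted over the list alone, camera adjusted p = 4.56e-06). An example was GFI1 at -0.50 ± 0.09. Of 24 MYC and nucleolar target genes, none rose, 20 fell and 4 did not pass (0 and 21 adjusted over the list alone, camera adjusted p = 5.31e-21), and MYC changed by -0.76 ± 0.15.

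Of 25 immediate early factors with bryostatin 1 in U937, 6 rose, 1 fell and 18 did not pass (6 and 1 adjusted over the list alone, camera adjusted p = 0.00394, adjusted p = 0.342 with an estimated correlation). Members included IER3 at 1.37 ± 0.15 and FOS at 0.46 ± 0.10. The ERK feedback list gave 3 rises, 1 fall and 14 that did not pass (4 and 1 adjusted over the list alone, camera adjusted p = 0.133). An example was DUSP10 at 1.37 ± 0.12. Of 23 unfolded protein and amino acid response genes, 7 rose, 1 fell and 15 did not pass (9 and 1 adjusted over the list alone, camera adjusted p = 3.16e-04). Examples were the cystine transporter SLC7A11 at 1.52 ± 0.07 and HERPUD1, a gene of protein degradation at the endoplasmic reticulum, at 0.54 ± 0.10. CDK inhibitors and arrest genes gave 4 rises, no falls and 12 that did not pass (4 and 0 adjusted over the list alone, camera adjusted p = 0.00492). An example was CDKN1A at 1.00 ± 0.09. In total 2463 genes differed from DMSO (limma), 1129 higher and 1334 lower, 64 and 8 of them at least 2-fold. The count was 4309 with the replicate block, 3784 with only the U937 arrays and 3938 with array weights.

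Merle 23 in U937, at 1000 nM for 8 h, gave changes of the size seen with PMA. CXCL10 rose by 6.17 ± 0.33, DCSTAMP by 3.73 ± 0.09, TNFAIP3 by 3.43 ± 0.20, MAML2 by 3.34 ± 0.18, IER3 by 3.23 ± 0.15, IL1B by 3.03 ± 0.16, TNF by 2.76 ± 0.26, CXCL8 by 2.40 ± 0.23 and MMP9 by 2.25 ± 0.08. P2RY2 changed by -1.75 ± 0.08, IRX3 by -1.35 ± 0.11 and MYC by -0.85 ± 0.15. EGR1 rose by 1.44 ± 0.37, FOS by 1.12 ± 0.10 and CDKN1A by 1.64 ± 0.09. Of 26 NF-kB targets, 23 rose, none fell and 3 did not pass (24 and 0 adjusted over the list alone, camera adjusted p = 2.60e-43). Of 33 monocyte and macrophage genes, 16 rose, 1 fell and 16 did not pass (16 and 1 adjusted over the list alone, camera adjusted p = 4.43e-12). MYC and its nucleolar targets gave no rises, 18 falls and 6 that did not pass (0 and 20 adjusted over the list alone, camera adjusted p = 1.52e-13). In all 3759 genes differed from DMSO (limma), 1806 higher and 1953 lower, 157 and 34 at least 2-fold. The count was 5653 with the replicate block and 5734 with array weights.

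At equal doses and times in U937, many immediate early factors were lower with bryostatin 1 than with PMA. TNF was lower with bryostatin 1 at -3.27 ± 0.26, a 9.67-fold difference, as were EGR1 at -2.37 ± 0.37, IL1B at -2.31 ± 0.16, IER3 at -1.93 ± 0.15, EGR3 at -1.69 ± 0.17 and RGS16, a regulator of G protein signalling, at -1.52 ± 0.11. The chemokine CCL20 differed by -1.17 ± 0.17, the EGF family ligand HBEGF by -1.13 ± 0.16, FOS by -0.57 ± 0.10, DUSP6 by -0.67 ± 0.15, CDKN1A by -0.55 ± 0.09 and the protein kinase D isoform PRKD2 by -0.82 ± 0.10. The receptor TNFRSF9 was higher by 0.92 ± 0.16, TENT5A by 0.80 ± 0.07, the complement gene C3 by 0.80 ± 0.08 and the receptor CD244 by 0.79 ± 0.06. Of 25 immediate early factors, none were higher with bryostatin 1, 14 lower and 11 did not pass (0 and 15 adjusted over the list alone, camera adjusted p = 1.45e-19). Of 18 ERK feedback genes, none were higher, 10 lower and 8 did not pass (0 and 11 adjusted over the list alone, camera adjusted p = 3.25e-12). NF-kB targets gave 1 higher, 12 lower and 13 that did not pass (1 and 13 adjusted over the list alone, camera adjusted p = 3.26e-16). Of 23 unfolded protein and amino acid response genes, 9 were higher, 3 lower and 11 did not pass (9 and 3 adjusted over the list alone, camera adjusted p = 0.00216). The chaperone HSPA5 was higher by 0.72 ± 0.07 and HERPUD1 by 0.68 ± 0.10, while the stress pseudokinase TRIB3 was lower at -0.77 ± 0.10. PKC and C1 domain genes gave none higher, 6 lower and 24 that did not pass (2 and 9 adjusted over the list alone, camera adjusted p = 0.00149). In total 1156 genes differed (limma), 456 higher with bryostatin 1 and 700 lower, of which none of the former and 19 of the latter differed at least 2-fold. The count was 2640 with the replicate block, 2165 with only the U937 arrays and 1984 with array weights.

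Between Merle 23 and PMA in U937, at 1000 and 100 nM, 0 genes passed limma's test, with 319 at an unadjusted p under 0.05. Chance alone would give more on average, a share of 0.05 of the 18377 genes. The test thus appeared conservative here, and 0 calls do not show equal effects. With the replicate block 853 genes had an unadjusted p under 0.05 in limma's test and 2 passed. With all probe sets of the deposited table tested 2 passed, and with array weights 1. The plain contrast of the one-way model called 0. TNF differed by -0.34 ± 0.26 (95% interval -0.86 to 0.19) and MMP9 by 0.26 ± 0.08 (0.09 to 0.42, adjusted p = 1.000, limma). The interval excluded a 2-fold difference for 18375 of 18377 genes and for all 172 of the genes that PMA changed at least 2-fold. Monocyte and macrophage genes had a median difference of 0.04, with none higher with Merle 23, none lower and 33 that did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 9.77e-04). Unfolded protein and amino acid response genes had one of 0.05, with none higher, none lower and 23 that did not pass (1 and 0 adjusted over the list alone, camera adjusted p = 4.14e-04). Merle 23 and bryostatin 1 differed in 889 genes of U937 (limma), 598 higher with Merle 23 and 291 lower, 17 of the former and none of the latter at least 2-fold. TNF was higher with Merle 23 by 2.94 ± 0.26, IL1B by 2.42 ± 0.16, EGR1 by 2.14 ± 0.37 and IER3 by 1.86 ± 0.15, and TENT5A and the protease gene PRSS12 were lower at -0.87 ± 0.07 and -0.79 ± 0.07. Immediate early factors gave 14 higher, none lower and 11 that did not pass (15 and 0 adjusted over the list alone, camera adjusted p = 1.45e-19). NF-kB targets gave 14 higher, none lower and 12 that did not pass (18 and 0 adjusted over the list alone, camera adjusted p = 1.17e-22). That count was 2197 with the replicate block, 1793 with only the U937 arrays and 2001 with array weights.

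The profile of Merle 23 in U937 lay at a distance of 0.116 from bryostatin 1. Its distance to PMA came out at -0.0350, where the sign marks a squared difference below that expected from array spread. The difference of 0.151 gave p = 0.00794 in the two-sided exact permutation test, the smallest it can give. With genes past an F test alone the exact p was 0.119, and with labels exchanged within replicate numbers it was 0.125, where the smallest possible is 0.0625. From differences within numbers the distances were 0.1253 to bryostatin 1 and 0.0205 to PMA. Merle 23 lay closer to PMA in 5 of 5 replicate numbers of U937.

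Genes called for more than 1 compound were counted against the same DMSO arrays. In LNCaP 2808 genes were called in the same direction for PMA and bryostatin 1 (89.0% of the bryostatin 1 calls), and 35 in opposite directions. PMA and Merle 23 shared 6277 (93.6% of the Merle 23 calls) and bryostatin 1 and Merle 23 shared 2769. In U937 the 3 counts were 1891, 3236 and 2001. Independent calls would share 241 rises and 441 falls for PMA and bryostatin 1 in LNCaP, and 107 and 141 in U937. In simulated unchanged LNCaP groups shared DMSO arrays gave a correlation across genes of 0.5. Few calls arise there, so 0 shared calls decide nothing. With DMSO arrays split between compounds, the median count was 1877.5 for PMA and bryostatin 1 in LNCaP and 1169.5 in U937. It was 1824 for bryostatin 1 and Merle 23 in LNCaP, and 2036 and 1239.5 for Merle 23 with PMA and with bryostatin 1 in U937. The covariance of PMA and bryostatin 1 effects over genes was 0.0938 in LNCaP and 0.0450 in U937, of which 0.00259 and 0.00174 came from shared controls. Less that part, the slope of bryostatin 1 on PMA effects was 0.358 in LNCaP (0.327 to 0.376 over left-out replicate numbers) and 0.670 in U937 (0.659 to 0.681). For Merle 23 on PMA it was 0.867 and 1.03. Genes are not independent replicates, so these slopes carry no p.

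**Figure D4:**
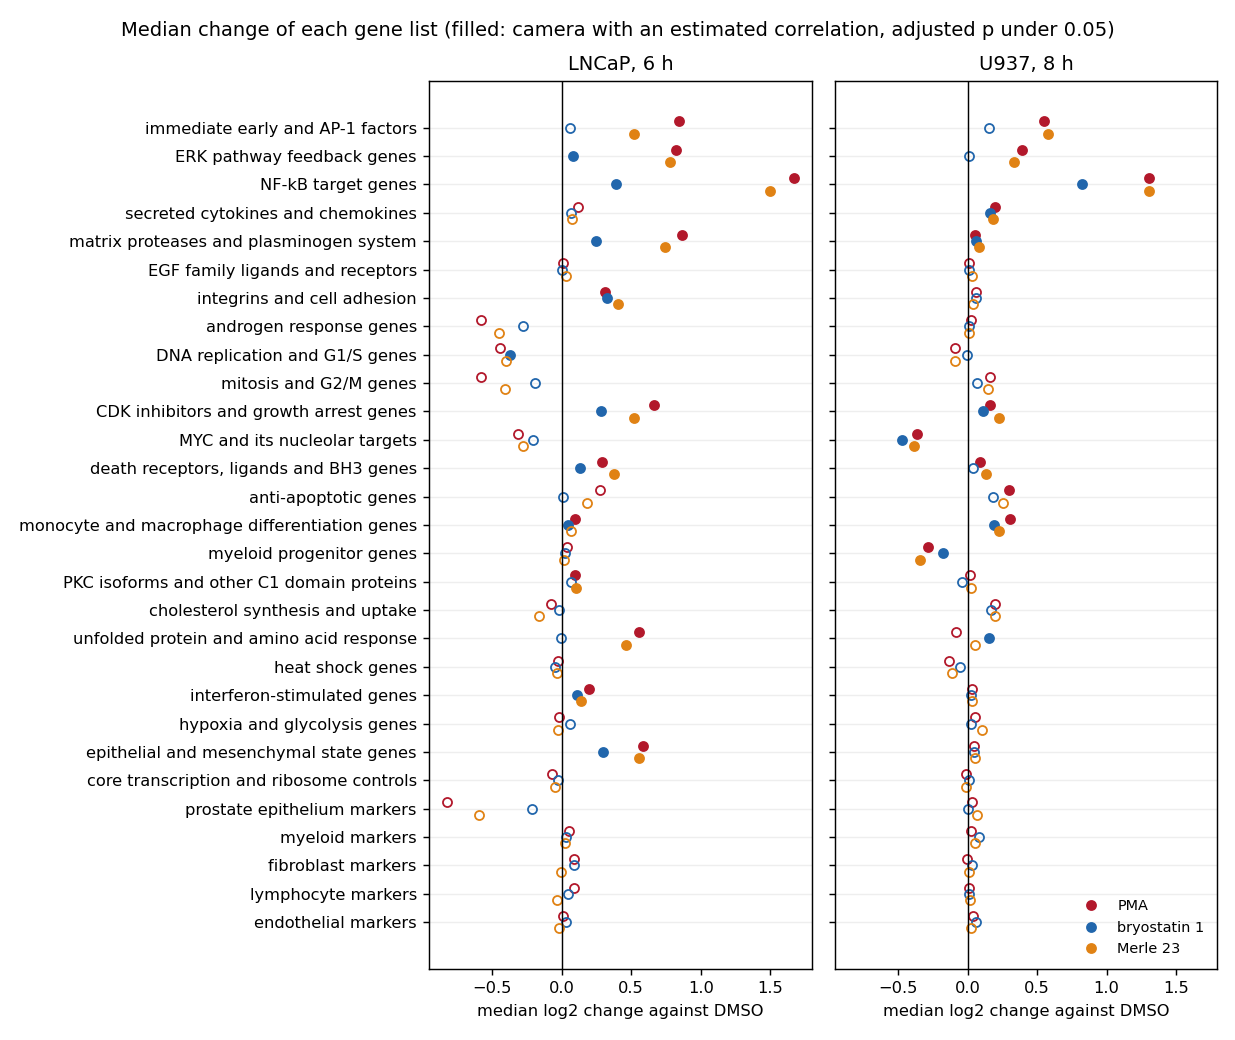
Median log2 change of the measured members of 29 gene lists with each compound against DMSO, in LNCaP at 6 h (left) and U937 at 8 h (right). Filled points mark where camera with an estimated correlation gave an adjusted p under 0.05. NF-kB targets stood at 1.67 with PMA and 0.39 with bryostatin 1 in LNCaP, and at 1.30 and 0.82 in U937.

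The last comparison set the U937 effect of a compound against its LNCaP effect, where line and time (8 h and 6 h) cannot be told apart. Of the 22 genes named for a difference between the lines, 15 lay below the array medians in all 4 groups of 1 line (group means up to 4.85), so their values below mostly restate the effect in the other line. In U937 these were CLDN1, ITGA2, SYTL2, MMP10, EDN1, KLK3, TCIM, CCN1, PTGFR and GRHL2, and in LNCaP DCSTAMP, MAML2, MMP9, GPR34 and IL1B. For PMA the effect in U937 minus that in LNCaP was -5.99 ± 0.18 for CLDN1, -5.81 ± 0.19 for ITGA2, -4.86 ± 0.17 for SYTL2, -4.80 ± 0.18 for MMP10 and -4.52 ± 0.24 for EDN1. CXCL10 (4.20 ± 0.47), ARRDC3 (3.68 ± 0.16), the membrane adaptor PAG1 (3.64 ± 0.11), DCSTAMP (3.48 ± 0.12) and MAML2 (3.19 ± 0.25) had the more positive effect in U937. MMP9 differed by 1.89 ± 0.12, CXCL8 by -1.65 ± 0.32, KLK3 by 1.36 ± 0.10 and MYC by 0.67 ± 0.21, while for TNF the difference was 0.26 ± 0.37 (adjusted p = 0.678, limma, 95% interval -0.49 to 1.00). Of 33 mitosis genes, 31 had the more positive effect in U937, none the more negative and 2 did not pass (31 and 0 adjusted over the list alone, camera adjusted p = 3.30e-18). The list of unfolded protein and amino acid response genes gave 1 more positive, 12 more negative and 10 that did not pass (1 and 12 adjusted over the list alone, camera adjusted p = 4.17e-05). Matrix protease genes gave 3 more positive, 10 more negative and 7 that did not pass (3 and 10 adjusted over the list alone, camera adjusted p = 1.67e-04). For bryostatin 1, CLDN1 differed by -3.80 ± 0.18, ITGA2 by -3.67 ± 0.19, MMP10 by -3.50 ± 0.18, RAET1L by -3.23 ± 0.17, CXCL10 by 4.26 ± 0.47, GPR34 by 2.71 ± 0.19, PAG1 by 2.61 ± 0.11, MMP9 by 1.97 ± 0.12 and MYC by -0.73 ± 0.21. For Merle 23, CLDN1 differed by -5.77 ± 0.18, ITGA2 by -5.67 ± 0.19, CXCL10 by 3.91 ± 0.47, DCSTAMP by 3.67 ± 0.12, PAG1 by 3.59 ± 0.11 and MMP9 by 2.24 ± 0.12.

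The difference between bryostatin 1 and PMA was also compared between the lines. It was higher in U937 than in LNCaP for EDN1 (4.27 ± 0.24), TCIM (3.36 ± 0.18), CCN1 (3.30 ± 0.24), TNFAIP3 (3.02 ± 0.28) and CXCL8 (2.42 ± 0.32). It was lower in U937 for ARRDC3 (-3.25 ± 0.16), PTGFR (-2.38 ± 0.13), IL1B (-2.15 ± 0.22), GRHL2 (-2.03 ± 0.11) and MYC (-1.40 ± 0.21). All but TNFAIP3, CXCL8, ARRDC3 and MYC lay below the array medians in every group of 1 line. For TNF the lines differed by -0.56 ± 0.37 (adjusted p = 0.354, limma, over the alternatives 0.538 down to 0.0140 with the replicate block). NF-kB targets gave 19 more positive, 1 more negative and 6 that did not pass (19 and 2 adjusted over the list alone, camera adjusted p = 8.58e-11). Unfolded protein and amino acid response genes gave 16 more positive, none more negative and 7 that did not pass (17 and 0 adjusted over the list alone, camera adjusted p = 3.85e-13). Between the lines 5732 genes differed in the effect of PMA, 2012 in that of bryostatin 1, 4946 in that of Merle 23 and 3462 in bryostatin 1 against PMA (limma). Upward differences numbered 3145, 1118, 2592 and 1722, and the replicate block gave 4105 for bryostatin 1 and 5587 for bryostatin 1 against PMA.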

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

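Tests of the LNCaP arrays numbered 1, the gene groups with bryostatin 1 and the unfolded protein genes follow patterns seen in the data. They count as chosen only after the results were seen. The gene lists, the contrasts, the tests and the alternatives not named as later additions were set before the data were examined.

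Among called genes that PMA changed at least 2-fold in LNCaP, bryostatin 1 gave a larger part of the PMA effect on matrix protease and integrin genes than on immediate early and NF-kB genes. Genes in both pairs of lists were left out. The slope of its effects on those of PMA was 0.595 ± 0.0989 for 16 genes of the former and 0.221 ± 0.101 for 27 of the latter (mean and SD over 5 replicate numbers). Genes outside the lists, matched on the PMA effect and the DMSO level, had slopes of 0.379 and 0.302, a difference of 0.0767. The lists differed by 0.298 ± 0.0380 more. Few other genes rose as much as ITGA2, so compression of large effects stays undecided. The slope was larger for protease and integrin genes in 5 of 5 numbers, by 0.374 ± 0.0308, and the smallest p an exact test over 5 numbers can give is 0.0625. A difference between the gene groups, such as slower decay of adhesion transcripts after an early signal, may account for this, and with 1 time per line that hypothesis was not tested.

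Of 23 unfolded protein and amino acid response genes, 9 were higher and 3 lower with bryostatin 1 than with PMA in U937, against 1 higher and 15 lower in LNCaP, with a camera adjusted p of 3.85e-13 for the difference between the lines (1.98e-04 with an estimated correlation). Leaving out each replicate number in turn gave adjusted p between 1.49e-13 and 3.77e-12, which argues against a single number as the cause. Higher need not mean raised over DMSO (HSPA5 was lower with PMA). Line and time (8 h in U937, 6 h in LNCaP) cannot be told apart. A later phase of the response in U937 could give the same values.

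The 4 LNCaP arrays numbered 1 lay apart from the other LNCaP arrays in every treatment, and the first component of the residuals, which sets them apart, held 48.7% of the residual variance. Their root mean square deviation was 0.214, against at most 0.120 for another number. After quantile normalization within the line the component held 49.4%. The deposited values had been through RMA, which already equalizes array distributions. The repeat could therefore change little and cannot decide whether normalization is the cause. Without the 223 small RNA genes the component held 45.8%, so these are not the whole pattern. Small RNA genes were shifted by a median of 0.495, above 100% of random lists, with VTRNA1-1 at 2.08 and RNU4-2 at 1.32, mitosis genes by -0.22 and markers of other cell types by at most 0.05. A shared culture or day of the number stays open. The lowest residual correlation among the 4 arrays, 0.694, restates that they lie together and does not support it, the labels give no dates, and no biological explanation was tested.

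Counts of called genes were set against 100 drawn splits of the same 10 arrays, the real split included. In LNCaP the real count and the highest of the other splits were 7769 and 5996 for PMA, 6705 and 5220 for Merle 23, 5237 and 3859 for bryostatin 1 against PMA and 4123 and 3712 for Merle 23 against bryostatin 1. In U937 they were 3675 and 1325 for PMA, 2463 and 796 for bryostatin 1, 3759 and 1641 for Merle 23, 1156 and 87 for bryostatin 1 against PMA and 889 and 39 for Merle 23 against bryostatin 1. In each of these 1 of 100 splits, the real one, gave so many. Arrays of the same number correlate, and the 16 splits that part all 5 numbers were always among those drawn. The shares are therefore not exact p-values. For bryostatin 1 in LNCaP 2 of 100 splits gave as many (3154 real, 3320 highest other), and for Merle 23 against PMA in LNCaP 4 of 100 (237 and 631). These shares lay under the 0.05 set beforehand, but in both contrasts another split called more genes than the real one. Chance is thus not excluded by the splits for these contrasts. Every split as large kept both arrays numbered 1 on the same side, and with the replicate block the counts were 5632 and 1276. The many calls in such splits point to a structure of the samples by number. For Merle 23 against PMA in U937 limma called 0 genes (319 at an unadjusted p under 0.05, fewer than chance gives on average, and 16 in the highest other split). Since all 100 splits give at least 0 genes by construction, the splits decide nothing there. Among the 16 splits that part all 5 numbers, which are too few for a share under 0.05, the highest others in LNCaP were 5029 for PMA, 497 for bryostatin 1, 3143 for Merle 23, 2343 for bryostatin 1 against PMA, 3 for Merle 23 against PMA and 1293 for Merle 23 against bryostatin 1. In the same order they were 768, 306, 934, 4, 0 and 1 in U937. For PMA, bryostatin 1, Merle 23 and bryostatin 1 against PMA, real counts between lines were 5732, 2012, 4946 and 3462. Residuals regrouped within lines gave at most 2075, 238, 3333 and 1995 (1 of 100 each as high, again not exact p-values).

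Of 426 groups of 5 arrays, 35 (8.22%) had 1 array far from the others by Dixon's ratio of gap to range, where chance gives about 1 in 20 groups. By ratio these were LNCaP DMSO replicate 1 high in CCL2 (0.805), EGR1 (0.827), NFKB2 (0.852), JUNB (0.830) and the array median (0.836) and low in POLR1B (0.758), BIRC2 (0.755) and SLC3A2 (0.859), LNCaP PMA replicate 1 high in ATF3 (0.744), TCIM (0.780) and GATA2 (0.817) and low in ITGA2 (0.797) and SYTL2 (0.827), LNCaP bryostatin 1 replicate 2 high in TNF (0.732), KLF6 (0.878), RSAD2 (0.877), TRAF1 (0.711) and PMAIP1 (0.756), and LNCaP Merle 23 replicate 1 low in CLDN1 (0.7101) and PRKCA (0.727). Others were LNCaP DMSO replicate 2 high in SYTL2 (0.780) and CXCL10 (0.838), LNCaP PMA replicate 2 high in RSAD2 (0.776) and low in IER3 (0.814), U937 bryostatin 1 replicate 3 high in CCL20 (0.761) and low in RAET1L (0.744), and U937 DMSO replicate 5 high in ITGAX (0.858) and MSMO1 (0.743). Others were U937 DMSO replicate 1 low in SYTL2 (0.782), LNCaP Merle 23 replicate 2 low in MMP10 (0.785), LNCaP bryostatin 1 replicate 4 low in FOS (0.806), and LNCaP DMSO replicate 5 high in DDIT3 (0.953). Others were LNCaP PMA replicate 4 high in HOXB13 (0.773), LNCaP DMSO replicate 3 low in MCL1 (0.732), and U937 DMSO replicate 2 low in MMP9 (0.744).

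Over the 4 comparisons, 39 effects of named genes (some genes in several comparisons) and the medians of 25 list results differed between the lines by limma's or camera's test of the difference, given as U937 minus LNCaP on the log2 scale. In 24 of the 39 effects the gene lay below the array medians in all groups of a line. That line is given above for each gene, so these differences reflect a gene without clear signal in 1 line. For PMA the genes were CXCL10 (4.20), ARRDC3 (3.68), PAG1 (3.64), DCSTAMP (3.48), MAML2 (3.19), EDN1 (-4.52), MMP10 (-4.80), SYTL2 (-4.86), ITGA2 (-5.81), CLDN1 (-5.99), MMP9 (1.89), CXCL8 (-1.65), KLK3 (1.36) and MYC (0.67). The list medians were matrix proteases (-0.41), integrins (-0.16), mitosis genes (0.78), the unfolded protein response (-0.46) and epithelial and mesenchymal genes (-0.44). For bryostatin 1 the genes were CXCL10 (4.26), GPR34 (2.71), PAG1 (2.61), RAET1L (-3.23), MMP10 (-3.50), ITGA2 (-3.67), CLDN1 (-3.80), MMP9 (1.97) and MYC (-0.73). The list medians were NF-kB targets (0.53), integrins (-0.37), replication genes (0.34), monocyte genes (0.10), progenitor genes (-0.19), PKC and C1 domain genes (-0.20) and epithelial and mesenchymal genes (-0.22). For Merle 23 the genes were CXCL10 (3.91), DCSTAMP (3.67), PAG1 (3.59), ITGA2 (-5.67), CLDN1 (-5.77) and MMP9 (2.24). The list medians were matrix proteases (-0.40), integrins (-0.16), PKC and C1 domain genes (-0.17), the unfolded protein response (-0.41) and epithelial and mesenchymal genes (-0.48). For bryostatin 1 against PMA the genes were EDN1 (4.27), TCIM (3.36), CCN1 (3.30), TNFAIP3 (3.02), ARRDC3 (-3.25), PTGFR (-2.38), IL1B (-2.15), GRHL2 (-2.03), CXCL8 (2.42) and MYC (-1.40). The list medians were NF-kB targets (0.73), matrix proteases (0.40), integrins (0.14), mitosis genes (-0.49), the unfolded protein response (0.54), interferon-stimulated genes (0.16), epithelial and mesenchymal genes (0.33) and prostate markers (-0.53).

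Probe sets without a gene name, 7807 in all, were outside the comparisons. Against DMSO 14.5%, 3.23% and 11.3% of them passed limma's test with PMA, bryostatin 1 and Merle 23 in LNCaP, and 4.82%, 2.88% and 5.14% in U937.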

How the results depend on the processing

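The alternatives without the 4 LNCaP arrays numbered 1, with squared distances and with labels exchanged within replicate numbers were chosen only after the results were seen. Of 584 recomputed values of 25 results (counts, distances, list calls and overlaps), 542 stayed within 1.5 times the count or on the same side of the test's threshold, 39 moved further, 2 fell below the threshold, 1 rose past it and 0 changed direction. For the changes below the cause was not tested, except where named.

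With the replicate number as a block, which removes spread shared within a number, counts of called genes were 5632 for bryostatin 1, 1276 for Merle 23 against PMA and 6342 for Merle 23 against bryostatin 1 in LNCaP. In U937 they were 5633 for PMA, 4309 for bryostatin 1, 5653 for Merle 23, 2640 for bryostatin 1 against PMA, 2 for Merle 23 against PMA and 2197 for Merle 23 against bryostatin 1. Between lines they were 4105 for bryostatin 1 and 5587 for bryostatin 1 against PMA. With only the arrays of the line the counts were 1978 for bryostatin 1 and 47 for Merle 23 against PMA in LNCaP, and 3784, 2165 and 1793 for bryostatin 1, bryostatin 1 against PMA and Merle 23 against bryostatin 1 in U937. With array weights they were 591 for Merle 23 against PMA in LNCaP and 3938, 5734, 1984, 1 and 2001 in U937 for bryostatin 1, Merle 23, bryostatin 1 against PMA, Merle 23 against PMA and Merle 23 against bryostatin 1. With all probe sets tested, Merle 23 against PMA in U937 gave 2. Without the 4 LNCaP arrays numbered 1, Merle 23 against PMA in LNCaP gave 447. Leaving out 1 array gave 121 (Merle 23 replicate 4) to 338 for that contrast, with 144 without PMA replicate 2 or Merle 23 replicate 3 and 156 without PMA replicate 4. No other count moved by over 1.5 times without 1 array, and those of PMA ran from 7256 to 8162 in LNCaP and from 3341 to 3583 in U937.

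The difference of squared distances for Merle 23 in LNCaP was 0.0691 (exact permutation p = 0.00794). With labels exchanged within numbers the distance difference in LNCaP was 0.185 (exact p = 0.438). In U937 it was 0.187 (exact p = 0.119) with genes past an F test alone, and 0.105 (exact p = 0.125) within numbers, where the few label exchanges cannot pass in either line. Without 1 array the planned difference ran from 0.198 to 0.296 in LNCaP and from 0.136 to 0.158 in U937. With an estimated correlation 108 list tests passed. Overlaps of genes changed at least 2-fold, fewer by construction, were 95, 718 and 97 in LNCaP and 62, 164 and 67 in U937, for PMA with bryostatin 1, PMA with Merle 23 and bryostatin 1 with Merle 23. With fewer DMSO arrays per contrast, split between compounds, the median overlap was 1824 for bryostatin 1 with Merle 23 in LNCaP and 1169.5, 2036 and 1239.5 in U937.

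For 319 values of named genes, 7169 of 7262 alternatives left direction and call as they were, 54 ended a call, 11 made one and 28 changed the sign of a gene that was not called, while 0 changed that of a called gene. Calls that ended in at least 1 alternative were those of TRAF1, ACP3, JUNB and KIF20A with bryostatin 1 in LNCaP (highest adjusted p 0.0679, 0.0805, 0.135 and 0.118), of ATF3, TCIM and FOS for Merle 23 against PMA in LNCaP (0.118, 0.0616 and 0.119), and in U937 of DNAJB9 with bryostatin 1 (0.0922), DNAJB9 and CXCL8 for bryostatin 1 against PMA (0.0615 and 0.0820) and CXCL8 and MMP9 for Merle 23 against bryostatin 1 (0.125 and 0.223). Signs changed for differences near 0. Without 1 array MYC with bryostatin 1 in LNCaP ran from -0.108 to 0.105, and in U937 TNF with bryostatin 1 from -0.418 to 0.0517, MMP9 and MYC for bryostatin 1 against PMA from -0.0883 to 0.0424 and -0.0775 to 0.0624, and CXCL8 and EGR1 for Merle 23 against PMA from -0.173 to 0.0605 and -0.469 to 0.0309. EGR1 between lines for bryostatin 1 against PMA ran from -0.310 to 0.115. With array weights MMP9 for bryostatin 1 against PMA in U937 was 0.00451, and with quantile normalization MYC was 0.00829.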

Other observations

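The lists in this part were set before the data were examined, and no tests in this part were chosen after a result was seen. Cholesterol synthesis and uptake genes moved in U937 at 8 h: of 21, 9 rose, 1 fell and 11 did not pass (9 and 2 adjusted over the list alone, camera adjusted p = 0.00305, adjusted p = 0.237 with an estimated correlation) with PMA and 7 rose, 1 fell and 13 did not pass (9 and 1 adjusted over the list alone, camera adjusted p = 1.69e-04, adjusted p = 0.126 with an estimated correlation) with bryostatin 1. HMGCS1, an early enzyme of the pathway, rose with PMA by 0.91 ± 0.12 in U937 and by 1.77 ± 0.12 in LNCaP, SQLE, the squalene epoxidase, by 0.87 ± 0.12 in U937, and MSMO1, a sterol oxidase, with bryostatin 1 by 0.98 ± 0.17 in U937. In LNCaP with PMA the list gave 2 rises, 9 falls and 10 that did not pass (2 and 9 adjusted over the list alone, camera adjusted p = 0.361). Hypoxia and glycolysis genes gave 9 rises, 4 falls and 9 that did not pass (9 and 5 adjusted over the list alone, camera adjusted p = 0.0445, adjusted p = 0.161 with an estimated correlation, adjusted p = 0.140 with the replicate block, median log2 -0.02 and mean 0.29 with the test pointing up) with PMA in LNCaP, where EGLN3, a prolyl hydroxylase of the hypoxia response, rose by 2.70 ± 0.10. In U937 they gave 6 rises, no falls and 16 that did not pass (6 and 0 adjusted over the list alone, camera adjusted p = 0.0250, adjusted p = 0.138 with an estimated correlation) with PMA. Heat shock genes gave 1 rise, 4 falls and 6 that did not pass (1 and 4 adjusted over the list alone, camera adjusted p = 0.875, median log2 -0.03 and mean 0.13 with the test pointing down) with PMA in LNCaP and no rises, 4 falls and 7 that did not pass (0 and 5 adjusted over the list alone, camera adjusted p = 0.0922) in U937. EGF family ligands and receptors gave 2 rises, 1 fall and 10 that did not pass (2 and 1 adjusted over the list alone, camera adjusted p = 0.537) in LNCaP and 2 rises, no falls and 11 that did not pass (2 and 0 adjusted over the list alone, camera adjusted p = 0.182) in U937 with PMA, and HBEGF rose in U937 by 1.91 ± 0.16. In LNCaP HBEGF likewise stood at 5.89 with DMSO and 7.79 with PMA.

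Core transcription and ribosome controls gave 4 rises, 4 falls and 7 that did not pass (4 and 4 adjusted over the list alone, camera adjusted p = 0.934, median log2 -0.07 and mean 0.01 with the test pointing down) with PMA in LNCaP and 1 rise, 1 fall and 13 that did not pass (1 and 1 adjusted over the list alone, camera adjusted p = 0.824, median log2 -0.01 and mean 0.01 with the test pointing up) in U937. Markers of cell types other than the line were read for PMA against DMSO. In LNCaP myeloid markers gave 3 rises, no falls and 10 that did not pass (1 and 0 adjusted over the list alone, camera adjusted p = 0.177), and CD68, a lysosomal marker of macrophages that other cells also express, rose by 3.26 ± 0.11. Fibroblast markers gave 3 rises, no falls and 7 that did not pass (3 and 0 adjusted over the list alone, camera adjusted p = 0.259) there, lymphocyte markers no rises, no falls and 9 that did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.498) and endothelial markers no rises, 1 fall and 9 that did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.959, median log2 0.01 and mean -0.01 with the test pointing down). In U937 prostate epithelium markers gave no rises, no falls and 12 that did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.923), and myeloid markers, of the line's own lineage, 5 rises, 2 falls and 6 that did not pass (5 and 4 adjusted over the list alone, camera adjusted p = 0.0320, adjusted p = 0.152 with an estimated correlation, adjusted p = 0.0674 with the replicate block). UHRF1, a replication-linked chromatin gene, changed by -0.68 ± 0.10 with bryostatin 1 in LNCaP, while its other probe set gave 0.05 and was not called.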
